A study of Mus musculus with 14 samples.

How the data were processed

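Per the labels' protocols, mouse embryonic fibroblasts (MEFs) from E13.5 embryos were grown in 3% O2, Tip60 deletion was induced with 250 nM 4-hydroxytamoxifen (4-OHT) for 3 or 5 days, and stranded poly(A) libraries were sequenced as 80 bp paired-end reads on an Illumina NextSeq instrument. The treatment text is the same for all 14 samples, and the labels do not say separately whether control cells received the drug. Per the submitters' processing notes, reads were assigned to genes of the mm10 genome with featureCounts. The aligner, the annotation release, the strand setting and the tool version are not given in the sources used here. The unit of the values the authors deposited is the count, an integer number of fragments or reads per gene, with no normalization. Per the file headers, each file holds a gene identifier, the gene's length and the count of 1 library.

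Each file had 27179 lines, of which 909 had no gene identifier and held 0.194% to 0.315% of a library's counts. These were left out, which left 26270 identifiers, 25275 of them with a symbol. Xist, Tsix and the genes of the Y chromosome (112 in the files) were kept out of the tests because the sexes are unequal between the groups. Expression is given as CPM, the count relative to a library's total, with totals scaled by the trimmed mean of M values (TMM) method.

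Differential expression was tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr, TMM scaling, 1 robust quasi-likelihood fit of all 14 libraries with 1 mean per group, and Benjamini-Hochberg adjustment over the tested genes of each contrast. A gene was called at an adjusted p below 0.05. The contrasts were KO against control at day 3 and at day 5, the difference between these effects, and day 5 against day 3 within each genotype. Log2 fold changes are those of the fit and carry their standard error (SE). Log2 CPM values use a prior count of 2, which the fold changes do not. The filter kept 14327 genes (14333 with the sex genes).

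Gene lists were written from general knowledge before the data were examined: 31 lists, of which 8 hold markers of other cell types. They cover the Tip60 complex, H2A.Z and its exchange, other lysine acetyltransferases, DNA replication, G1/S, mitosis, inhibitors of cyclin-dependent kinases (CDKs), p53 targets, homologous recombination and Fanconi genes, other DNA repair, senescence-associated secreted factors, interferon and inflammation, ribosomal proteins, ribosome biogenesis and Myc, the unfolded protein and integrated stress responses, apoptosis, extracellular matrix, contractile SRF and YAP targets, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, autophagy and lysosome, NRF2 targets, and markers of cartilage and bone, skeletal muscle, macrophages, endothelium, neural and glial cells, epithelium, adipocytes, and blood and liver. Of 837 members, 834 were matched by symbol. The blood and liver list had 0 tested members and 30 lists were tested with camera (preset correlation 0.01, adjusted over the lists), and again with a correlation estimated per list. Counts "adjusted over the list alone" come from Benjamini-Hochberg adjustment within the list.

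Genes named in the text follow a rule fixed together with the lists. Kat5 is always named. For KO against control, the 6 most strongly raised and the 6 most strongly lowered called genes are named, if their mean was at least 2 CPM, all libraries of one group lay on one side of the other, and the symbol was not a clone or predicted-gene name. The other contrasts have 3 in each direction. For each list a few called members with the smallest adjusted p qualified. Those printed were picked from them and are not always the ones with the very smallest. Every tested CDK inhibitor is named. Col2a1, Comp, Acan, Hapln1 and, in control cells, Txnip were chosen after their values were seen. Some genes that the rule selects are not reported.

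A fold against a group with no counts is given as at least the ratio to a floor of 3 counts over the group, and folds against 1 to 3 counts have a 95% counting interval. These intervals and floors cover counting error only, since the libraries had no molecular identifiers. The tests treat libraries as independent, whereas the libraries of replicates 1 and 2 of the day 3 controls have the same embryo label and several embryos were sampled at both days. Their p values describe these cultures better than the populations of mice behind them. Count profiles differed beyond sampling noise for every pair of libraries within a group (chi-square per degree of freedom 3.29 to 79; 15.9 for the day 3 controls with a common label), so no file was a copy of another of its group.

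Embryo identifiers in the labels pair the days within a genotype. After group means were removed, paired libraries correlated at -0.017, -0.023 and 0.204 in KO and at 0.02, 0.077 and -0.023 in control, so the counts gave little sign of the pairing. Between genotypes the replicate number is shared but the embryos are not. The litter numbers of the labels overlap between genotypes, while the leading numbers of the embryo identifiers (136, 153 and 159 against 218 and 219) do not, and the genotypes were read as having no litter in common. KO libraries were male in 5 of 7 and control libraries in 1 of 7.

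The alternatives were relative log expression (RLE) scaling, no filter, a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0, limma voom with embryo as a random effect (correlation 0.04), sex as a covariate, the sex genes kept, only the groups compared, the day 3 controls of one label summed, a test against a minimum fold of 1.5 (glmTreat), a block for replicate number (KO against control) or for embryo label (the other contrasts), and each library left out. Lists were also tested with fry and with a prior count of 0.5. Chosen after seeing the data were counts thinned to the smallest total and the omission of KO day 3 replicate 3 together with control day 5 replicate 4. The code was tested on simulated data with 200 changed genes of 14327: a 2-fold change was recovered in 65.7%, 82.1%, 58.2%, 70.1% and 77.6% of genes for KO against control at day 3 and day 5, the difference between days, and day 5 against day 3 in KO and in control. A 1.5-fold change was recovered in 35.8%, 55.2%, 10.4%, 37.3% and 37.3%. Of the calls, 4.4% to 7% were false. A list of 30 genes shifted by 1.5-fold was called in every contrast and 0 of the other 29 lists were. The simulated genes varied independently, whereas estimated correlations within the real lists reached 0.787. The simulation therefore does not measure false list calls in these data. The simulated libraries were independent too, with no embryo or litter effect, and far fewer genes changed than were called here. Its share of false gene calls therefore need not hold for these data.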

Results

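Gene expression was measured by RNA-seq in 14 libraries of mouse embryonic fibroblasts (MEFs), with or without the lysine acetyltransferase Tip60. Tip60 is encoded by Kat5 and is the catalytic subunit of a complex that acetylates histones H4 and H2A and exchanges H2A.Z. Deletion was induced with 4-hydroxytamoxifen (4-OHT), a ligand commonly used to switch on a Cre recombinase fused to the oestrogen receptor, and cells were collected 3 or 5 days after its start. The groups were control (Tip60+/+) at day 3 (n = 3), KO (Tip60-/-) at day 3 (n = 3), control at day 5 (n = 4) and KO at day 5 (n = 4). Most embryos contributed a library at each day. Control libraries came from embryos of litters 218 and 219 and KO libraries from litters 136, 153 and 159, as read from the embryo identifiers, and the replicates 1 and 2 of the day 3 controls have the same identifier. Males made up 5 of 7 KO and 1 of 7 control libraries.

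Total counts per library were 9160637, 12908651 and 10876494 in control at day 3 (replicates 1 to 3), 39203154, 2187168 and 10488613 in KO at day 3 (replicates 2 to 4), 15287262, 19310829, 6064694 and 14517811 in control at day 5 (replicates 1 to 4) and 27172076, 13452590, 19136434 and 15437988 in KO at day 5 (replicates 1 to 4). KO day 3 replicate 3 was the shallowest. After filtering, 14327 genes were tested.

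Kat5 mRNA was lower in every KO library than in every control library at both days (gene identifier 81601; mm10 chromosome 19, 5603014 to 5611556). At day 3 it was 19.9 ± 1.41 CPM in KO and 31.9 ± 0.41 CPM in control (SD, n = 3 each), or 62.3% of control (log2 fold change -0.68 ± 0.086 SE, adjusted p = 2.02e-05; exact permutation p = 0.1, the smallest that 20 labelings allow). At day 5 it was 18.4 ± 1.14 CPM against 30.9 ± 0.923 CPM (n = 4 each), or 59.6% of control (-0.75 ± 0.071, adjusted p = 1.59e-06; exact permutation p = 0.0286 of 70 labelings). Single KO libraries ranged from 17.3 to 21.1 CPM and control libraries from 29.8 to 32.3 CPM. The deleted exons are not given in the sources used here, and a gene-level count also holds reads from outside the deleted part, so the remaining share does not measure the share of cells that kept the gene.

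**Figure D1:**
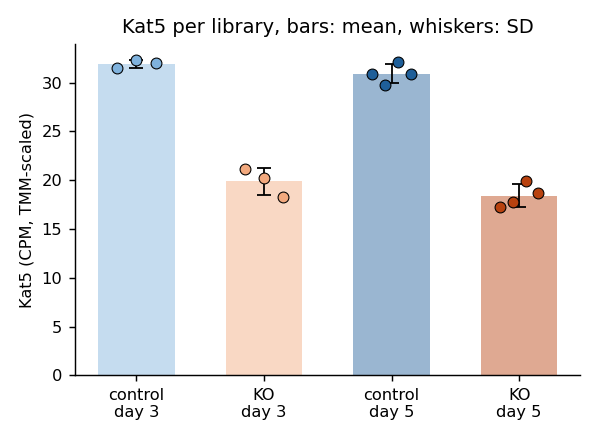
Kat5 in each library, in CPM with TMM scaling. Bars show group means and whiskers the SD, with n = 3 at day 3 and n = 4 at day 5 per genotype.

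The first principal component, which held 53% of the variance, separated KO from control and, among controls, day 3 from day 5. Control libraries at day 3 lay at 67.8 to 74.3, day 5 controls of litter 218 at 33 to 39.7, and all KO libraries at -58.9 to -26.1. The day 5 control of litter 219 (replicate 4, the single male control) lay at 0.1, between the other controls and KO. The second component held 15.8%.

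**Figure D2:**
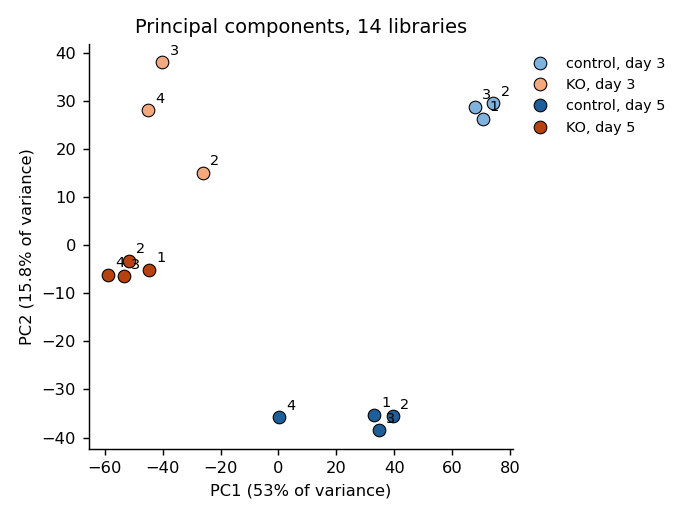
Principal components of log2 CPM of the tested genes. Points are libraries, numbered by replicate, with 1 colour for each combination of genotype and day.

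The comparison at day 3 asks which genes respond early to the loss of Tip60. In KO cells the unfolded protein and integrated stress list was lower almost as a whole, and many ribosomal, glycolysis and cholesterol synthesis genes were lower. Most mitotic and cartilage genes and some recombination, interferon and matrix genes were higher. With an estimated correlation only the stress list was called, and the other lists named here had adjusted p values of 0.282 to 0.723. The Tip60 complex beyond Kat5 was not shifted as a list, with members changed in both directions. In all, 7288 of 14327 genes changed (3529 higher and 3759 lower in KO; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 2279 did so by more than 1.5-fold under glmTreat. The groups did not overlap for 8282 genes (57.8%, against 10% by chance), 6837 of them called.

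The genes most strongly raised at day 3 encode secreted, membrane and metabolic proteins of varied function. Lctl, a member of the klotho family, had no counts in control and rose at least 55.8-fold (log2 fold change 9.72 ± 2.495, adjusted p = 0.00881). Cldn11, a tight junction claudin, went from 0.0779 to 32.2 ± 14.2 CPM (8.33 ± 0.586, adjusted p = 2.95e-07), a ratio of 288 with a counting interval of 98.4 to 1400. Ism1, a secreted isthmin, rose by 8.03 ± 0.736 (adjusted p = 2.57e-06; ratio 250, interval 68.9 to 2070), and Scara5, a ferritin receptor, by 7.49 ± 1.07 (adjusted p = 0.00014). The aldehyde dehydrogenase gene Aldh1a7 rose by 7.34 ± 2.05 (adjusted p = 0.0109; ratio 110, interval 30.3 to 914). Pcsk2, a prohormone convertase, rose by 7.30 ± 2.119 (adjusted p = 0.0132; ratio 157, interval 27.9 to 6230), a call that was lost without KO replicate 4 (adjusted p = 0.0518) or control replicate 2 (adjusted p = 0.0503).

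Among the most strongly lowered genes at day 3 was Derl3, which acts in degradation of misfolded proteins at the endoplasmic reticulum. It fell from 11.1 ± 2.61 to 0.272 CPM (-5.17 ± 0.517, adjusted p = 2.94e-06). The adaptor gene Sh2d6 fell from 23.4 ± 3.87 to 1.45 CPM (-4.31 ± 0.504, adjusted p = 1.45e-05). Also lower were Cass4, a scaffold of focal adhesions (-4.11 ± 0.462, adjusted p = 8.03e-06), Prr32 (-3.91 ± 0.437, adjusted p = 7.61e-06), the phosphatase regulator Ppp1r16b (-3.75 ± 0.531, adjusted p = 5.73e-05) and Mei4, known for meiotic DNA breaks (-3.51 ± 0.356, adjusted p = 3.34e-06).

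The unfolded protein and integrated stress list was lower almost as a whole at day 3: 28 of 29 tested members fell and 0 rose (median -1.42, camera adjusted p = 3.71e-16, adjusted p = 0.000432 with an estimated correlation, 28 adjusted over the list alone). It was the only list called with an estimated correlation. Hsp90b1, the chaperone Grp94, fell from 5856 ± 401 to 1612 ± 105 CPM (-1.86 ± 0.104, adjusted p = 3.09e-08). Ppp1r15a, the stress-induced phosphatase subunit Gadd34, fell by 2.04 (± 0.109, adjusted p = 2.28e-08) and Chac1, an ATF4 target that degrades glutathione, by 2.00 (± 0.121, adjusted p = 5.67e-08).

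Many genes of growth and metabolism were also lower at day 3. Of ribosomal proteins, 43 of 53 fell and 0 rose (median -0.92, camera adjusted p = 2.39e-09, adjusted p = 0.653 with an estimated correlation), among them Rps18 (-1.03, adjusted p = 7.62e-05). Of the ribosome biogenesis and Myc list, 32 of 41 fell and 1 rose (camera adjusted p = 1.16e-08, adjusted p = 0.59 with an estimated correlation), with the nucleolar GTPase Gnl3 at -1.32 (adjusted p = 1.76e-06). Of glycolysis and hypoxia genes, 21 of 31 fell and 1 rose (median -0.88, camera adjusted p = 8.33e-07, adjusted p = 0.59 with an estimated correlation), including aldolase C, Aldoc (-2.72 ± 0.229, adjusted p = 6.46e-07), and the lactate exporter Slc16a3 (-1.72 ± 0.164, adjusted p = 2.27e-06). Of cholesterol synthesis genes, 13 of 24 fell and 0 rose (camera adjusted p = 0.00227, adjusted p = 0.723 with an estimated correlation), including farnesyl diphosphate synthase, Fdps (-1.48 ± 0.244, adjusted p = 0.00032). Of autophagy and lysosome genes, 14 of 30 fell and 3 rose (camera adjusted p = 0.00878, adjusted p = 0.723 with an estimated correlation), and the lysosomal cholesterol transporter Npc1 fell by 1.21 (± 0.08, adjusted p = 1.21e-07). In these lists 51 ribosomal protein, 35 ribosome biogenesis, 25 glycolysis, 13 cholesterol and 18 lysosome genes passed when adjusted over the list alone.

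Mitotic genes at day 3 were mostly higher in KO. Of the mitosis list, 38 of 58 genes rose and 0 fell (median 0.62, camera adjusted p = 4.36e-06, adjusted p = 0.723 with an estimated correlation, 41 adjusted over the list alone). The kinetochore gene Nuf2 rose from 7.66 to 19.2 CPM (1.37 ± 0.196, adjusted p = 6.09e-05) and the mitotic kinase gene Plk1 from 9.19 to 16.4 CPM (0.88 ± 0.157, adjusted p = 0.000387). DNA replication genes were mixed, with 14 of 47 higher and 5 lower (camera adjusted p = 0.0534, 18 adjusted over the list alone). That list was called when KO replicate 3 (adjusted p = 0.0214), KO replicate 4 (adjusted p = 0.0174) or control replicate 2 (adjusted p = 0.0463) was left out, and with sex as a covariate (adjusted p = 0.000118). The ribonucleotide reductase gene Rrm2 rose by 1.29 (± 0.176, adjusted p = 5.22e-05), whereas the helicase gene Mcm2 was lower (-1.19, adjusted p = 0.000112). Of G1/S genes, 8 of 19 rose and 4 fell (camera adjusted p = 0.422, 12 adjusted over the list alone).

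Of 7 CDK inhibitor genes at day 3, 3 rose and 1 fell (camera adjusted p = 0.655, 4 adjusted over the list alone). Cdkn2c (p18) rose by 1.73 (adjusted p = 6.01e-06), Cdkn2b (p15) by 0.47 (adjusted p = 0.00137) and Cdkn1b (p27) by 0.38 (adjusted p = 0.0196). The Cdkn1b call was lost without KO replicate 2 (adjusted p = 0.0563) or control replicate 2 (adjusted p = 0.0978), and with sex as a covariate (0.29, adjusted p = 0.0755). Cdkn1a (p21), the p53 target, was lower (-0.62, adjusted p = 3.48e-05). No change was called for Cdkn2a (-0.18, adjusted p = 0.333; -0.37 and adjusted p = 0.0251 with sex as a covariate), Cdkn2d (-0.16, adjusted p = 0.565) or Cdkn1c (0.14, adjusted p = 0.694).

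DNA damage and inflammatory genes changed in both directions at day 3. Homologous recombination and Fanconi genes were higher in 15 of 40 and lower in 1 (camera adjusted p = 0.00227, adjusted p = 0.723 with an estimated correlation), with the recombination mediator Brca2 at 1.48 ± 0.168 (adjusted p = 8.37e-06). Of p53 targets, 18 of 34 fell and 6 rose (camera adjusted p = 0.0755), and the death receptor gene Fas was among those that rose (1.98 ± 0.222, adjusted p = 7.66e-06). Of interferon and inflammation genes, 22 of 42 rose and 0 fell (median 1.01, camera adjusted p = 0.000994, adjusted p = 0.723 with an estimated correlation), with the chemokine gene Cxcl10 at 3.27 ± 0.567 (adjusted p = 0.000397). Of secreted factors of senescent cells, 17 of 34 rose and 4 fell (median 0.95, camera adjusted p = 0.00227, adjusted p = 0.282 with an estimated correlation), with the growth factor binding protein Igfbp5 at 2.09 ± 0.206 (adjusted p = 3.51e-06). Adjusted over the list alone, 16 recombination, 24 p53, 23 interferon and 25 secreted factor genes passed.

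Some matrix and contractile genes and most cartilage markers rose at day 3. Of matrix genes, 18 of 34 rose and 4 fell (camera adjusted p = 0.00269, adjusted p = 0.558 with an estimated correlation, 22 adjusted over the list alone), including the collagen gene Col3a1 (1.90 ± 0.235, adjusted p = 2.03e-05). Of contractile SRF and YAP targets, 12 of 29 rose and 3 fell (camera adjusted p = 0.0353, adjusted p = 0.764 with an estimated correlation, 15 adjusted over the list alone). That call was lost without KO replicate 2 (adjusted p = 0.297), control replicate 2 (adjusted p = 0.106) or control replicate 3 (adjusted p = 0.0717). Of cartilage and bone markers, 11 of 12 rose (median 3.65, also with zero-count members at their bound; camera adjusted p = 5.14e-05, adjusted p = 0.282 with an estimated correlation, 11 adjusted over the list alone). Col2a1, the collagen of cartilage, went from 76.4 to 2281 ± 171 CPM (4.90 ± 1.094, adjusted p = 0.00298) and the cartilage matrix gene Comp from 1.00 to 87.7 CPM (6.42 ± 1.525, adjusted p = 0.00437), both chosen after their values were seen.

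The machinery around Tip60 shifted in part at day 3. Besides Kat5, the complex had 3 of 17 genes higher and 5 lower (camera adjusted p = 0.752, 7 adjusted over the list alone), with Morf4l2, its MRG-domain subunit, at -0.74 ± 0.069 (adjusted p = 1.69e-06) and the scaffold gene Epc1 at 0.61 ± 0.088 (adjusted p = 6.65e-05). Of genes for H2A.Z and its exchange, 9 of 15 fell and 2 rose (camera adjusted p = 0.0395, adjusted p = 0.282 with an estimated correlation, 11 adjusted over the list alone), with the H2A.Z reader Pwwp2a at -0.92 (adjusted p = 1.72e-06) and the INO80 subunit Ino80c at 1.01 (adjusted p = 1.37e-05). Other lysine acetyltransferases were lower in 4 of 10 (camera adjusted p = 0.57, 6 adjusted over the list alone). Of NRF2 targets, 4 of 19 rose and 5 fell (camera adjusted p = 0.86, 9 adjusted over the list alone), although the quinone reductase gene Nqo1 rose by 1.37 (± 0.164, adjusted p = 1.34e-05). Camera called 16 of 30 lists at day 3, and up to 14 for other splits of the same 6 libraries. No litter held both genotypes.

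**Figure D3:**
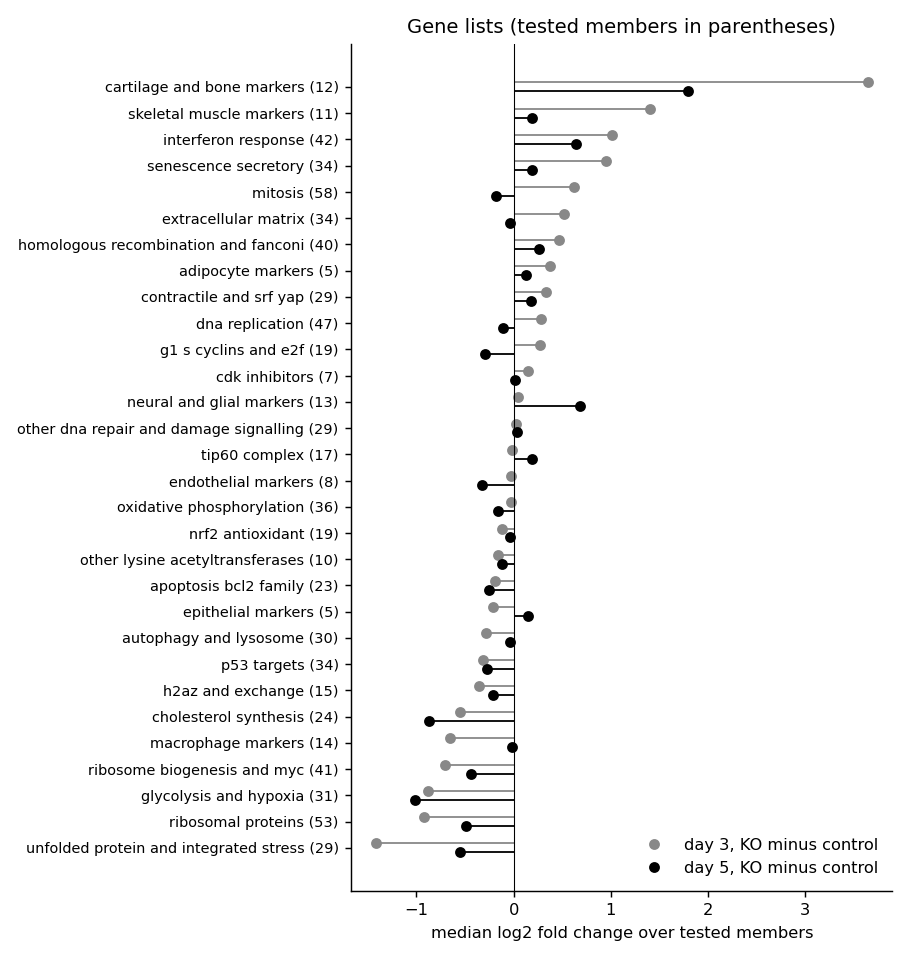
Median log2 fold change of KO against control over the tested members of each gene list. Grey marks day 3 and black marks day 5.

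The comparison at day 5 asks which changes are present after longer loss of Tip60. Most glycolysis, cholesterol synthesis, ribosome biogenesis and stress response genes and some ribosomal protein genes were lower in KO, and most cartilage markers were higher. Mitotic genes, mostly higher at day 3, no longer were, and some G1/S genes were lower. With an estimated correlation only the stress list was called, and the other lists of these that camera called had adjusted p values of 0.489 to 0.862. In all, 7519 of 14327 genes changed (3769 higher and 3750 lower in KO; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 1710 by more than 1.5-fold under glmTreat. The groups did not overlap for 6788 genes (47.4%, against 2.86% by chance), 6294 of them called.

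Cldn11 was the most strongly raised gene under the naming rule at day 5 (6.84 ± 0.44, adjusted p = 1.45e-07). The organic anion transporter gene Slco1a4 rose from 0.134 to 7.38 ± 2.29 CPM (5.57 ± 0.438, adjusted p = 1.01e-06) and the aldehyde dehydrogenase gene Aldh3a1 from 0.177 to 8.71 ± 1.74 CPM (5.51 ± 0.577, adjusted p = 4.79e-06). Scube1, a secreted EGF-domain protein, rose from 1.11 ± 0.422 to 22.8 ± 3.09 CPM (4.29 ± 0.245, adjusted p = 2.47e-08). The peptide transporter gene Slc15a2 (3.95 ± 0.86, adjusted p = 0.0023) and the galactosidase-like gene Glb1l2 (3.72 ± 0.433, adjusted p = 9.07e-06) followed.

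Genes of folate metabolism, lactate export and secretion were among the most strongly lowered at day 5. The GDP-dissociation inhibitor gene Arhgdig fell from 7.74 ± 0.335 to 1.04 ± 0.0839 CPM (-2.87 ± 0.169, adjusted p = 2.96e-08), the vesicle priming gene Unc13a by 2.83 (± 0.388, adjusted p = 8.76e-05) and the peptide hormone gene Adm2 by 2.74 (± 0.284, adjusted p = 3.31e-06). Aldh1l2, a mitochondrial folate enzyme under ATF4, fell from 128 ± 9.26 to 20 ± 1.33 CPM (-2.68 ± 0.085, adjusted p = 1.35e-10), and Slc16a3 from 320 ± 68.1 to 51.0 ± 5.92 CPM (-2.65 ± 0.146, adjusted p = 2.42e-08).

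Many metabolic and growth genes were lower at day 5. Of glycolysis and hypoxia genes, 26 of 31 fell and 0 rose (median -1.02, camera adjusted p = 2.81e-10, adjusted p = 0.489 with an estimated correlation), with Aldoc at -2.45 ± 0.212 (adjusted p = 7.33e-07). Of cholesterol synthesis genes, 22 of 24 fell and 0 rose (median -0.87, camera adjusted p = 5.86e-07, adjusted p = 0.645 with an estimated correlation), with Fdps at -1.48 ± 0.21 (adjusted p = 9.54e-05). Of the ribosome biogenesis and Myc list, 31 of 41 fell and 2 rose (camera adjusted p = 5.86e-07, adjusted p = 0.645 with an estimated correlation), including the pyrimidine synthesis gene Cad (-1.09, adjusted p = 2.64e-06) and spermidine synthase, Srm (-1.11, adjusted p = 1.18e-05). Of ribosomal proteins, 26 of 53 fell and 0 rose (median -0.49, camera adjusted p = 3.28e-05, adjusted p = 0.862 with an estimated correlation), among them Rpl4 (-0.76, adjusted p = 6.16e-06). Oxidative phosphorylation genes fell in 17 of 36 and rose in 2 (camera adjusted p = 0.0249, adjusted p = 0.862 with an estimated correlation; adjusted p = 0.0808 without KO replicate 2), with the ATP synthase subunit Atp5b at -0.60 (adjusted p = 0.000134). In these lists 27 glycolysis, 23 cholesterol, 33 ribosome biogenesis, 26 ribosomal protein and 19 oxidative phosphorylation genes passed when adjusted over the list alone.

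The unfolded protein and integrated stress list stayed lower at day 5, with 21 of 29 genes lower and 2 higher (median -0.56, camera adjusted p = 3.27e-06, adjusted p = 0.0287 with an estimated correlation, 24 adjusted over the list alone). The stress transcription factor gene Atf5 fell by 1.43 (± 0.1, adjusted p = 1.45e-07) and the serine synthesis gene Psat1 by 1.28 (± 0.102, adjusted p = 3.47e-07). NRF2 targets were split, with 6 of 19 higher and 6 lower (camera adjusted p = 0.944, 12 adjusted over the list alone). Higher were Gclc, the rate-setting enzyme of glutathione synthesis (0.76 ± 0.063, adjusted p = 5.01e-07), the cystine importer Slc7a11 (2.30 ± 0.226, adjusted p = 5.02e-06) and Nqo1 (0.87, adjusted p = 7e-05).

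Cell cycle genes were lower in part at day 5. Of G1/S genes, 10 of 19 fell and 2 rose (camera adjusted p = 0.0249, adjusted p = 0.489 with an estimated correlation, 12 adjusted over the list alone), with Cdk4 at -0.74 (adjusted p = 1.02e-06) and Ccne1, cyclin E1, at -0.52 (adjusted p = 6.42e-05). Of mitosis genes, 13 of 58 fell and 1 rose (camera adjusted p = 0.0827, 13 adjusted over the list alone), and without control replicate 4 there were 28 lower (camera adjusted p = 0.00062). The list was also called without KO replicate 4 (adjusted p = 0.0445). With sex as a covariate 7 of its genes were lower and 1 higher, and its median was 0.055 against -0.19 in the main fit. Of DNA replication genes, 13 of 47 fell and 2 rose (camera adjusted p = 0.166, 9 adjusted over the list alone), and without control replicate 4 there were 23 lower (camera adjusted p = 0.000702). With sex as a covariate 7 replication genes were lower and 6 higher, and the median was 0.002 against -0.11. The ubiquitin-conjugating gene Ube2c (-0.81, adjusted p = 0.00045), Plk1 (-0.51, adjusted p = 0.00238) and Mcm2 (-0.76, adjusted p = 0.000689) were lower.

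Of 7 CDK inhibitor genes at day 5, 3 rose and 3 fell (camera adjusted p = 0.837, 6 adjusted over the list alone). Cdkn2b (0.75, adjusted p = 7.92e-06), Cdkn2c (0.51, adjusted p = 0.00799) and Cdkn1b (0.29, adjusted p = 0.0319) rose. The Cdkn1b call was lost with sex as a covariate (0.21, adjusted p = 0.116) and without any of KO replicates 3 and 4 and control replicates 2 and 3. Cdkn1a (-0.80, adjusted p = 9.18e-07), Cdkn2a (-0.70, adjusted p = 0.000459) and Cdkn2d (-0.44, adjusted p = 0.00689; -0.0013 and adjusted p = 0.997 in thinned counts) were lower, and Cdkn1c did not change (0.02, adjusted p = 0.967). Of p53 targets, 17 of 34 fell and 5 rose (camera adjusted p = 0.0249, adjusted p = 0.645 with an estimated correlation, 23 adjusted over the list alone). Without control replicate 4, 18 p53 targets fell and 10 rose (camera adjusted p = 0.146).

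Some repair and inflammatory genes were higher in KO at day 5, and matrix genes were mixed. Homologous recombination and Fanconi genes were higher in 12 of 40 and lower in 2 (camera adjusted p = 0.0249, adjusted p = 0.862 with an estimated correlation; adjusted p = 0.254 without control replicate 4), with Brca2 at 0.73 (adjusted p = 0.000362). Interferon and inflammation genes were higher in 13 of 42 and lower in 1 (camera adjusted p = 0.0249, adjusted p = 0.918 with an estimated correlation; adjusted p = 0.304 without control replicate 4 and 0.11 without KO replicate 2). The chemokine gene Ccl5 rose by 1.96 (± 0.31, adjusted p = 0.000133) while the interferon-induced gene Ifit2 fell by 1.01 (± 0.184, adjusted p = 0.000501). Adjusted over the list alone, 14 recombination and 10 interferon genes passed. Secreted factors of senescent cells were higher in 9 of 34 and lower in 4 (camera adjusted p = 0.402, 11 adjusted over the list alone), with Igfbp4 at 1.98 ± 0.217 (adjusted p = 1.02e-05). Matrix genes were higher in 5 of 34 and lower in 11 (camera adjusted p = 0.68, 16 adjusted over the list alone), or higher in 14 and lower in 11 without control replicate 4, and the proteoglycan gene Lum rose by 2.01 (± 0.38, adjusted p = 0.000921).

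Cartilage and bone markers were higher in 8 of 12 at day 5 (median 1.79, camera adjusted p = 0.000686, adjusted p = 0.489 with an estimated correlation, 10 adjusted over the list alone). Without control replicate 4 all 12 were higher, with a median of 2.30. Col2a1 was at 776 ± 1133 CPM in control and 2585 ± 768 CPM in KO (log2 fold change 1.74 ± 0.822, adjusted p = 0.0958), and 3.63 with an adjusted p of 0.000113 without control replicate 4. For Comp the difference was 2.17 (± 0.918, adjusted p = 0.0662), and 5.22 with an adjusted p of 2.73e-05 without that library.

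Morf4l2, Epc1 and Ino80c kept their directions at day 5. The complex had 6 of 17 genes higher and 2 lower (camera adjusted p = 0.171, 8 adjusted over the list alone), with Morf4l2 at -0.94 ± 0.059 (adjusted p = 5.38e-08) and Epc1 at 0.81 (adjusted p = 1.21e-06). Of genes for H2A.Z and its exchange, 9 of 15 fell and 2 rose (camera adjusted p = 0.166, 11 adjusted over the list alone), with the SRCAP complex subunit Znhit1 at -0.90 (adjusted p = 3.49e-06) and Ino80c at 0.93 (adjusted p = 4.36e-06). Camera called 11 of 30 lists at day 5, and up to 12 for other splits of the same 8 libraries. In the means of the ribosome biogenesis, cholesterol, glycolysis and cartilage lists control replicate 4 lay nearer to KO than to the other controls, and in that of the mitosis list it lay below KO.

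**Figure D4:**
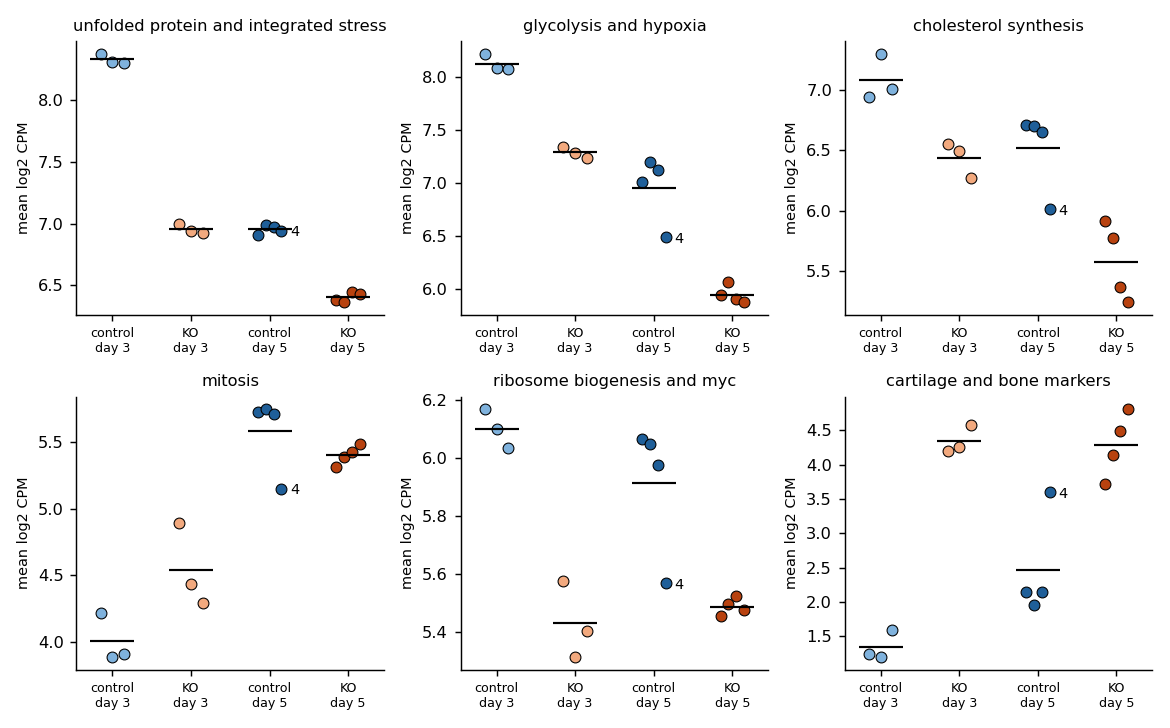
Mean log2 CPM of 6 gene lists in each library, with bars at the group means. The day 5 control of litter 219 is marked 4.

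The overlap of the 2 days asks how much of the KO effect lasted. Of the called genes, 2235 were higher at both days (928 if the days were independent), 2473 were lower at both (984 if independent) and 202 changed in opposite directions. Log2 fold changes correlated across genes at 0.721 (Pearson) and 0.704 (Spearman), with no library in common between the days. With different embryos at each day, 731 genes were higher at both (193 if independent), 1085 lower at both (265 if independent) and 29 opposite, and the correlation was 0.614. The day 3 controls of that comparison had the same embryo label. Litter 218 gave controls at both days, so a litter difference from KO would also be shared.

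The difference between the KO effects at day 5 and at day 3 asks which responses were early or late. The KO deficit in stress response genes shrank between the days, and the KO excess of mitotic and matrix genes was lost or reduced. With an estimated correlation the difference was called for the stress list (adjusted p = 0.000803) and not for the mitosis (adjusted p = 0.506) or matrix list (adjusted p = 0.233). In the stress list the control cells moved more than the KO cells. In all, 2051 of 14327 genes differed (1026 more positive and 1025 more negative at day 5; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 167 of them by more than 1.5-fold under glmTreat. Without control day 3 replicate 3 there were 1275.

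The stress list became less negative in 19 of 29 genes and more negative in 0 (median 0.84, camera adjusted p = 2.62e-14, adjusted p = 0.000803 with an estimated correlation, 19 adjusted over the list alone). Derl3 showed the strongest positive shift under the naming rule (5.70 ± 0.742, adjusted p = 0.00033): it was at 11.1 CPM in control at day 3 and at 0.272, 0.303 and 0.417 CPM in KO at day 3, control at day 5 and KO at day 5. Mitosis genes became more negative in 29 of 58 and more positive in 0 (median -0.83, camera adjusted p = 2.62e-14, adjusted p = 0.506 with an estimated correlation, 47 adjusted over the list alone). Plk1 was at 9.19 CPM in control and 16.4 CPM in KO at day 3, and at 45.3 and 31.9 CPM at day 5. Matrix genes became more negative in 12 of 34 (median -0.56, camera adjusted p = 3.39e-06, adjusted p = 0.233 with an estimated correlation, 14 adjusted over the list alone). The chitin-binding gene Fibcd1 (3.47 ± 0.598, adjusted p = 0.0021) and Sh2d6 (3.32 ± 0.693, adjusted p = 0.00701) shifted upward, and the membrane protein gene Tmem100 shifted downward (adjusted p = 0.004). Tmem100 had no counts in control at day 3 and was at least 32.3-fold higher in KO then and 5.19-fold higher at day 5, so that its KO effect was at least 6.23-fold smaller at day 5. Aldh1a7 (-7.72 ± 2.345, adjusted p = 0.0478) and the chemokine gene Cxcl5 (-6.15 ± 1.827, adjusted p = 0.044; adjusted p = 0.233 with the embryo block) also shifted downward, with calls that most single omissions removed. Kat5 did not differ between the days (-0.06, adjusted p = 0.759).

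Day 5 against day 3 within KO cells asks how cells without Tip60 changed in culture. Most mitotic and some replication genes rose, and most glycolysis and cholesterol genes and some stress response genes fell. With an estimated correlation only the stress list was called, and the others had adjusted p values of 0.0801 to 0.265. In all, 1725 of 14327 genes changed (713 higher and 1012 lower at day 5; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 138 of them by more than 1.5-fold under glmTreat. Without KO day 3 replicate 4 there were 1024, and 1104 and 1107 without KO day 5 replicates 3 and 4. The groups did not overlap for 3849 genes (26.9%, against 5.71% by chance), 1654 of them called.

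Of mitosis genes in KO, 47 of 58 rose (median 0.80, camera adjusted p = 9.38e-29, adjusted p = 0.25 with an estimated correlation), as did 22 of 47 DNA replication genes (median 0.55, camera adjusted p = 4.27e-16, adjusted p = 0.265 with an estimated correlation) and 15 of 40 recombination genes (camera adjusted p = 6.17e-09, adjusted p = 0.25 with an estimated correlation). Of glycolysis and hypoxia genes, 30 of 31 fell (median -1.29, camera adjusted p = 4.02e-33, adjusted p = 0.0801 with an estimated correlation), as did 20 of 24 cholesterol genes (median -0.79, camera adjusted p = 3.31e-14, adjusted p = 0.265 with an estimated correlation) and 16 of 29 stress genes (median -0.50, camera adjusted p = 2.15e-12, adjusted p = 0.00172 with an estimated correlation). In these lists 54 mitosis, 38 replication, 19 recombination, 30 glycolysis, 24 cholesterol and 21 stress genes passed when adjusted over the list alone. Txnip, which restrains glucose uptake and binds thioredoxin, rose from 6.03 to 117 ± 20.2 CPM (4.26 ± 0.579, adjusted p = 0.00073). U90926 (2.85 ± 0.536, adjusted p = 0.00333) and Clca3a2, of the chloride channel accessory family (2.08 ± 0.295, adjusted p = 0.00043), also rose. Kbtbd11, encoding a Kelch and BTB protein (-4.34 ± 0.397, adjusted p = 2.54e-05), Adm2 (-3.71 ± 0.293, adjusted p = 3.62e-06) and Fam169a (-3.70 ± 0.352, adjusted p = 1.92e-05) were the most strongly lowered under the naming rule.

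Day 5 against day 3 within control cells asks how cells with Tip60 changed in culture. The whole stress list fell and nearly the whole mitosis list rose, both farther at the median than in KO. With an estimated correlation that difference was called for the stress list (adjusted p = 0.000803) and not for the mitosis list (adjusted p = 0.506). In all, 5481 of 14327 genes changed (2625 higher and 2856 lower at day 5; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 1141 of them by more than 1.5-fold under glmTreat. The groups did not overlap for 6120 genes (42.7%, against 5.71% by chance), 5035 of them called.

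Of mitosis genes in control, 57 of 58 rose (median 1.62, camera adjusted p = 7.67e-31, adjusted p = 0.4 with an estimated correlation), as did 41 of 47 DNA replication genes (median 1.05, camera adjusted p = 1.55e-15, adjusted p = 0.422 with an estimated correlation) and 12 of 19 G1/S genes, with 1 lower (camera adjusted p = 1.29e-05, adjusted p = 0.132 with an estimated correlation). All 29 stress genes fell (median -1.27, camera adjusted p = 3.03e-22, adjusted p = 0.00011 with an estimated correlation), as did 28 of 31 glycolysis genes (median -1.10, camera adjusted p = 2.24e-13, adjusted p = 0.4 with an estimated correlation) and 41 of 53 ribosomal protein genes, with 1 higher (camera adjusted p = 2.61e-08, adjusted p = 0.569 with an estimated correlation). Adjusted over the list alone, 58 mitosis, 41 replication, 13 G1/S, 29 stress, 29 glycolysis and 48 ribosomal protein genes passed. Lowered most under the naming rule were Car6, a secreted carbonic anhydrase (from 36.7 ± 0.218 to 0.754 CPM; -5.62 ± 0.334, adjusted p = 3.9e-08), Derl3 (-5.20 ± 0.437, adjusted p = 8.67e-07) and the receptor cofactor gene Nrip2 (-4.63 ± 0.317, adjusted p = 1.26e-07). Raised most were Aldh1a7 (6.46 ± 2.066, adjusted p = 0.0277; ratio 96, interval 26.4 to 796), the complement regulator C4bp (5.58 ± 2.006, adjusted p = 0.0457; ratio 50.8, interval 17.2 to 248) and Cxcl5 (4.98 ± 1.516, adjusted p = 0.0219). Each of these 3 calls was lost without any of the day 3 controls. Aldh1a7 (adjusted p = 0.0844) and C4bp (adjusted p = 0.152) also lost theirs without control day 5 replicate 4, and C4bp (adjusted p = 0.105) and Cxcl5 (adjusted p = 0.151) with the embryo block.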

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

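Tests of other explanations were written after the result had been seen, except the splits of the libraries, the sex of the embryo for control day 5 replicate 4 and the comparison of litter 218 with the others over all called genes, which were written before. The litter comparison over cartilage and bone markers alone was written after.

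Of 158 checks of a group for a library standing apart, 16 were positive, and chance marks about 1 in 20 groups. In control at day 5, replicate 4 stood apart on the first principal component (0.1, others 33 to 39.7) and replicate 3 on the second (-38.5, others -35.7 to -35.2). Mean log2 CPM of gene lists in replicate 4 was apart for DNA replication (4.42, others 4.97 to 5.05), mitosis (5.15, others 5.71 to 5.75), p53 targets (6.15, others 5.98), other DNA repair (4.55, others 4.70 to 4.73), secreted factors of senescent cells (5.02, others 5.54 to 5.55), cholesterol synthesis (6.01, others 6.65 to 6.71) and cartilage and bone markers (3.59, others 1.96 to 2.15). Ribosomal proteins were apart in control day 5 replicate 1 (5.57, others 5.31 to 5.35). Among single genes, replicate 4 was apart for Aldoc (2.90, others 3.59 to 3.73), Plk1 (5.20, others 5.56 to 5.63), Mcm2 (5.75, others 6.35 to 6.44), Brca2 (3.68, others 4.15 to 4.16) and Cdkn1c (4.50, others 5.50 to 5.67), and replicate 3 for Glb1l2 (-2.94, others -1.18 to -1.02).

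Control day 5 replicate 4 may be a control culture in a different state. A mislabelled KO library does not account for it, since its Kat5 was 30.9 CPM, above the highest day 5 KO library (19.9 CPM) by 9.62 KO SDs. The place of replicate 4 on the first component was 40.6% of the way to KO. Of 138 genes far higher in KO, 51.4% rose in it by less than 50% of that share. The place rests on log values and the rise of a gene on linear ones. This count by itself therefore cannot exclude KO cells or RNA mixed into the library. Over these genes the library rose unevenly, by a median of 19.4% of the way to the KO level (quartiles 7.38% to 46.7%). Its Kat5 lay within the range of the other day 5 controls (29.8 to 32.1 CPM), which argues against a large share of KO RNA. A small share stays open. The library's deviation correlated with the male minus female difference of KO libraries at 0.125 at day 3 and 0.288 at day 5. Sex cannot be told apart from litter or culture as the cause. Litter 219 and the male sex occur in no other control.

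The smaller KO effect on the stress list at day 5 could be a change with time that both genotypes share and that went farther in control. Without the shallow KO day 3 library the median difference was 0.77, and without control day 5 replicate 4 it was 0.83, against 0.84 with all libraries, so neither library accounts for it. The changes with time in KO and control, which have no library in common, correlated across genes at 0.411 (Pearson; 0.376 Spearman), with 403 genes higher and 693 lower in both (131 and 202 if independent) and 78 opposite. The stress list fell by a median of 0.50 in KO and 1.27 in control. A state of high stress and low proliferation in the day 3 control cultures would give this pattern whether or not Tip60 set it.

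Genes differed widely at day 5, and some of that may be litter. Over 8376 genes called without it, the litter 219 control lay at a median 0.67 from KO (0) to the litter 218 controls (1). At 62.1% of those genes it lay nearer the other controls. Single litter 218 controls left out in turn lay at 1.00 to 1.08. Their scale differs, since its end at 1 included the litter 219 control and the genes were those called without each. Over cartilage and bone markers the litter 219 control lay at 0.52 (quartiles 0.03 to 0.93), with 6 of 12 nearer KO, so genotype and litter cannot be told apart there. With sex as a covariate 6422 calls (85.4%) were made in the same direction, and in thinned counts 4390 (58.4%), so neither sex nor library size accounts for most of them.

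The grouping of the libraries was set against other splits of the same sizes, all of them except for the difference between days, where 100 were drawn. For genes at day 5 the real grouping called 7519 genes and the highest other split 688, so 1 of 35 splits reached the real count. For day 5 against day 3 it was 1 of 35 in KO (highest other 5) and 1 of 35 in control. The highest other in control, 2440, came from a split placing control day 5 replicate 4 with the day 3 controls. Embryos pair the days, and only 8 splits in KO and 12 in control, the real one included, part as many embryo pairs. The real count was the highest of these too, but they are too few to judge by. At day 3 only 10 splits exist, too few to judge by: 1 of 10 reached the real count of 7288 genes (highest other 0) and 1 of 10 the real count of 16 lists (highest other 14). For the 11 lists called at day 5, 13 of 35 splits gave as many and the highest other gave 12, so the number of lists called by camera at day 5 may come from how these libraries happen to group and adds nothing to the gene counts. For the difference between days, 4 of 100 splits reached the real 2051 genes, and the highest other gave 4539. In the 3 splits above the real count, 0 or 1 of 3 KO libraries kept the KO label at day 3 and 3 or 4 of 4 at day 5. By construction such splits take up the genotype effect that both days share, and their counts reflect that structure of the samples.

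The difference between the KO effects of the days, called in 2051 genes, stood in 16 lists. Their median differences were 0.84 for the stress list, 0.38 for ribosomal proteins, 0.18 for ribosome biogenesis and Myc, 0.18 for autophagy and lysosome, 0.21 for the Tip60 complex, 0.60 for macrophage markers, -0.83 for mitosis, -0.39 for DNA replication, -0.33 for G1/S, -0.75 for secreted factors of senescent cells, -0.56 for matrix, -0.27 for contractile genes, -0.25 for cholesterol synthesis, -0.09 for oxidative phosphorylation, -0.69 for skeletal muscle markers and -1.62 for cartilage and bone markers. With an estimated correlation the stress list alone kept its call (adjusted p = 0.000803), and the others had adjusted p values of 0.233 to 0.787.

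Of 73 named genes, 28 had different KO effects at the 2 days, against 2051 of 14327 over all genes. The named genes were chosen from the same fits, some of them for the size of this difference, so the 2 shares cannot be compared. Differences in log2 fold change were positive for Derl3 (5.70), Ppp1r16b (5.15), Fibcd1 (3.47), Sh2d6 (3.32), Prr32 (3.22), Slc7a11 (1.76), Ppp1r15a (1.59), Hsp90b1 (1.23), Npc1 (1.05), Chac1 (0.84), Pwwp2a (0.70), Gnl3 (0.59) and Gclc (0.55). They were negative for Aldh1a7 (-7.72), Tmem100 (fitted at -6.40 with a group at 0 counts, a ratio of at least 6.23), Cxcl5 (-6.15), Ism1 (-5.02), Adm2 (-1.63), Col3a1 (-1.54), Fas (-1.50), Nuf2 (-1.45), Plk1 (-1.38), Rrm2 (-1.27), Cdkn2c (-1.21), Igfbp5 (-1.20), Ccne1 (-0.96), Slc16a3 (-0.93) and Brca2 (-0.76).

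Xist was at 5.96 CPM (13 counts, lower limit 3.18) in KO day 3 replicate 3, labelled male, against 0.138 CPM (upper limit 0.499) in the male control and 448 to 892 CPM in females.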

How the results depend on the processing

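Thinned counts and the joint omission of KO day 3 replicate 3 and control day 5 replicate 4 were chosen only after the result was seen, and the other alternatives were set in advance. Over 109 named gene and comparison pairs, 102 of them called, 2164 alternatives gave the same call in 2042, lost it in 100, gained it in 13 and turned its direction in 9; 28 pairs lost a call at least once. Requiring more than 1.5-fold (glmTreat) left 2279 genes at day 3 (60.2% higher), 1710 at day 5 (61.9% higher), 167 for the difference, 138 for time in KO (11.6% higher) and 1141 for time in control, by construction of the test. Thinned counts left 4743, 4590, 851, 920 and 3374, by loss of depth. Kat5 at day 3 stayed at -0.68 but was not called beyond 1.5-fold (adjusted p = 0.25). An estimated correlation left 1 list at day 3 and 1 at day 5, and fry called 17 and 14. At day 3 fry lost interferon (adjusted p = 0.051) and contractile genes (0.0589) and gained p53 targets (0.00282), apoptosis (0.0127) and acetyltransferases (0.0127). At day 5 it lost interferon genes (0.151) and gained the Tip60 complex (0.004), H2A.Z exchange (8.92e-05), secreted factors (0.0324) and apoptosis (8.92e-05). In thinned counts the calls of Ccne1 (-0.26, adjusted p = 0.19) and Cdkn2d (-0.0013, adjusted p = 0.997) at day 5 and of Derl3 (adjusted p = 0.0595), Sh2d6 (adjusted p = 0.195) and Tmem100 (adjusted p = 0.115) for the difference were lost. With different embryos 1816 genes changed in the same direction at both days, from 2 libraries per group.

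Leaving out single libraries gave 6244 to 6786 genes at day 3, 6502 to 8376 at day 5, 1275 to 2750 for the difference, 1024 to 1605 for time in KO (29.3% higher at the lowest, against 41.3%) and 4362 to 5686 for time in control; the cause was not tested. Cdkn1c, uncalled throughout, turned negative at day 3 with the number block (-0.068) and without KO replicate 4 (-0.014; highest 0.32, without KO replicate 2), and at day 5 with DESeq2 (-0.0026) and without KO replicate 1 (-0.12), KO replicate 2 (-0.01) or control replicate 4 (-0.19; highest 0.15, without KO replicate 4); the cause was not tested. The Kat5 difference between days turned to 0.004 without KO day 3 replicate 2 and 0.011 in thinned counts, and was lowest without KO day 3 replicate 4 (-0.13); the cause was not tested.

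A block for replicate number gave 6223 genes at day 3 and 7264 at day 5, and a block for embryo label gave 1561 for the difference, 1777 for time in KO and 4293 for time in control. Between genotypes the number does not stand for an embryo; libraries with the same number correlated at -0.051 and -0.021 at day 3 and at 0.23, 0.155, -0.166 and 0.428 at day 5. The number block called 16 and 12 lists: at day 3 it lost H2A.Z exchange (adjusted p = 0.0791) and gained DNA replication (adjusted p = 0.0176), and at day 5 it gained mitosis (adjusted p = 0.0446). With adjusted p in brackets, the embryo block lost for the difference the ribosome biogenesis (0.217), contractile (0.205), oxidative phosphorylation (0.13) and macrophage (0.205) lists and gained recombination (0.0163), interferon (0.00339) and glycolysis (0.00339). For time it gained muscle markers in KO (0.034) and other DNA repair in control (0.0451) and lost contractile genes in control (0.0788). Among named genes the number block gained Cdkn2a at day 3 (-0.34, adjusted p = 0.024) and Col2a1 (2.82, adjusted p = 0.0126) and Comp (3.34, adjusted p = 0.0105) at day 5, and lost Col2a1 at day 3 (5.32, adjusted p = 0.142), and the embryo block lost Cxcl5 in both its comparisons and C4bp. The blocks changed no other call named in the report.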

Other observations

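Of the tests behind this part, the day-to-day correlation, the litter position over cartilage markers and the values of single cartilage genes were chosen only after the result was seen.

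Of the markers of other cell types that the report does not describe, the macrophage and skeletal muscle lists were called in KO against control at day 3 and not at day 5. Macrophage markers were lower in 7 of 14 and higher in 0 at day 3 (camera adjusted p = 0.0187, adjusted p = 0.723 with an estimated correlation, 8 adjusted over the list alone), a call lost without KO replicate 2 (adjusted p = 0.07) or control replicate 2 (adjusted p = 0.0644), and at day 5 in 3 of 14, with 1 higher (camera adjusted p = 0.69, 2 adjusted over the list alone). Skeletal muscle markers were higher in 6 of 11 at day 3 (median 1.40, camera adjusted p = 0.0444, adjusted p = 0.282 with an estimated correlation, 7 adjusted over the list alone), a call lost without KO replicate 2 (adjusted p = 0.0989) or control replicate 3 (adjusted p = 0.0605) and with a prior count of 0.5 (adjusted p = 0.0511), and at day 5 in 3 of 11, with 1 lower (camera adjusted p = 0.741, 3 adjusted over the list alone). Not called at day 3 and day 5 were endothelial (1 of 8 higher and 1 lower, camera adjusted p = 0.933; then 2 and 2, adjusted p = 0.883), neural and glial (2 of 13 higher and 2 lower, adjusted p = 0.933; then 2 and 2, adjusted p = 0.69), epithelial (1 of 5 higher and 1 lower, adjusted p = 0.86; then 2 and 1, adjusted p = 0.69) and adipocyte markers (1 of 5 higher and 1 lower, adjusted p = 0.752; then 2 and 0, adjusted p = 0.69). Adjusted over the list alone, these 4 lists had 2, 4, 2 and 3 genes at day 3 and 4, 3, 3 and 2 at day 5.

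Apoptosis genes of the BCL2 family were higher in 4 of 23 and lower in 9 at day 3 (camera adjusted p = 0.57) and higher in 4 and lower in 12 at day 5 (adjusted p = 0.166). Oxidative phosphorylation genes at day 3 were higher in 3 of 36 and lower in 7 (adjusted p = 0.655). Other DNA repair genes were higher in 8 of 29 and lower in 6 at day 3 (adjusted p = 0.853), and higher in 5 and lower in 4 at day 5 (adjusted p = 0.93). At day 5, contractile genes were higher in 5 of 29 and lower in 5 (adjusted p = 0.741), or 9 and 5 without control replicate 4. Autophagy and lysosome genes at day 5 were higher in 4 of 30 and lower in 7 (adjusted p = 0.675). Other lysine acetyltransferases were then higher in 3 of 10 and lower in 4 (adjusted p = 0.68). In these lists 13 and 16 apoptosis, 13 and 8 repair and, at 1 day, 8 oxidative phosphorylation, 10 contractile, 9 lysosome and 7 acetyltransferase genes passed when adjusted over the list alone. The median, the mean and camera differed in sign for epithelial markers at day 3 and for endothelial markers, CDK inhibitors, NRF2 targets and other DNA repair genes at day 5.

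Time in culture moved further lists in both genotypes. In KO, ribosomal proteins fell in 10 of 53 (camera adjusted p = 0.00228, adjusted p = 0.76 with an estimated correlation), matrix genes in 10 of 34 (adjusted p = 1.77e-07, adjusted p = 0.157 with an estimated correlation), lysosome genes in 6 of 30 (adjusted p = 0.00111, adjusted p = 0.63 with an estimated correlation) and interferon genes in 2 of 42 (adjusted p = 0.00659, adjusted p = 0.76 with an estimated correlation), whereas G1/S genes rose in 7 of 19 and fell in 1 (adjusted p = 0.00659, adjusted p = 0.25 with an estimated correlation) and other DNA repair genes rose in 2 of 29 (adjusted p = 0.0167, adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone, 11, 13, 8, 2, 8 and 1 of these passed. In control, lysosome genes fell in 19 of 30 and rose in 2 (adjusted p = 4.95e-06, adjusted p = 0.457 with an estimated correlation), cholesterol genes fell in 13 of 24 (adjusted p = 0.000733, adjusted p = 0.594 with an estimated correlation), recombination genes rose in 22 of 40 and fell in 1 (adjusted p = 3.69e-06, adjusted p = 0.437 with an estimated correlation), and cartilage markers rose in 4 of 12 (median 1.05, also with zero-count members at their bound; adjusted p = 0.0289, adjusted p = 0.569 with an estimated correlation). Contractile genes rose in 13 of 29 and fell in 2 (adjusted p = 0.0106, adjusted p = 0.637 with an estimated correlation; adjusted p = 0.0788 with the embryo block), and secreted factors of senescent cells rose in 10 of 34 and fell in 4 (adjusted p = 0.0289, adjusted p = 0.437 with an estimated correlation). Adjusted over the list alone, 23, 14, 23, 4, 16 and 16 of these passed. Txnip in control rose from 1.74 to 13.2 ± 12.4 CPM (2.91 ± 0.67, adjusted p = 0.00485).

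Day 3 control cultures may have been starved or dense. They held the highest expression of unfolded protein, integrated stress and glycolysis genes and the lowest of mitosis genes, and both genotypes moved the same way with time (correlation 0.411 across genes). Derl3, Car6 and Nrip2 were highest in the day 3 controls, at 11.1, 36.7 and 14.3 CPM. These genes were named for falling most with time in control, so their high level there adds no support. Low Txnip there (1.74 CPM) is what low glucose would give, since glucose induces Txnip. Mean Txnip was also lower in KO at day 3 than in either genotype at day 5. At both days it was lower in control than in KO, so glucose cannot be told apart here from a genotype or litter difference. Ribosomal protein and cholesterol synthesis genes were highest in the day 3 controls too (mean log2 CPM 5.66 to 6.31 and 6.94 to 7.30). Growth and metabolic genes were thus not low there as a whole. Repeating day 3 with both genotypes plated at matched density and fed the day before, with glucose and cell number recorded, would separate culture state from loss of Tip60.

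Cartilage genes in KO may reflect litter or dissection rather than Tip60. Over these markers the litter 219 control lay at 0.52 of the way from KO to the other controls (quartiles 0.03 to 0.93). That control was nearer KO at 6 of 12 markers, so the genes printed next do not stand for all of them. In the litter 219 control Col2a1 was 2470 CPM (other day 5 controls 211 ± 88.6, KO 1710 to 3550), Comp 57.6 CPM (2.22 ± 0.901, KO 39.1 to 123), Acan 12.7 CPM (1.12 ± 0.177, KO 11.6 to 31.3) and Hapln1 15 CPM (1.12 ± 0.526, KO 13.3 to 19.3). MEFs of littermates with both genotypes, or the same KO embryo with and without 4-OHT, would test it.

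Lower glycolysis, cholesterol and ribosome biogenesis genes at both days might be targets of Myc, HIF1 or SREBP2 that need Tip60 as a coactivator. In thinned counts 4390 of the day 5 calls were made in the same direction, so depth alone does not explain most of them. Litter or culture state stays open: in the litter 219 control, with Kat5 at 30.9 CPM, mean log2 CPM was 5.57 for ribosome biogenesis (KO 5.46 to 5.52, other day 5 controls 5.97 to 6.07), 6.01 for cholesterol synthesis (KO 5.25 to 5.92, others 6.65 to 6.71) and 6.49 for glycolysis (KO 5.87 to 6.06, others 7.01 to 7.20). Chromatin immunoprecipitation of Tip60 and acetylated H2A.Z at Slc16a3, Fdps and Cad soon after the deletion would tell direct from secondary effects. Counting dividing cells at each day would show whether the lower G1/S genes at day 5 go with slower growth.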
